A study of Homo sapiens with 11 samples.

How the data were processed

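RNA was measured in 11 captured regions of distal bronchiolar epithelium, 8 from IPF lungs and 3 from healthy lungs. Per the labels' protocols, the tissue was fixed in paraformaldehyde and embedded in paraffin, and libraries were made with the GeoMx whole transcriptome panel for human RNA. Per the submitters' processing notes, bcl2fastq 2.19.1.403 and the hg38 build were used. The aligner or counter, and whether duplicate reads were removed, are not given in the sources used here. Per the series' design, regions were chosen as ciliated. The labels do not say how regions map to people; they carry a number that is the same in all 3 healthy regions, in IPF regions 1 to 4 and in IPF regions 5 to 8.

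The deposited table holds a signal value for each of 11127 genes in each region. Per the file's name, the authors scaled the values to the third quartile (Q3) and removed background, and what the removal took out is not stated. Negative-probe values were not analysed here. In every region 100% of values were whole multiples of the region's smallest value (tolerance 0.001), so whole reads were recovered by dividing by it. The smallest recovered count was 1 and no value was 0; whether counts of 0 were set to 1 is not stated. 3 note columns with 7 filled cells were not used. Total reads ran from 54851 to 157596 per region, with a median of 6 reads per gene over all regions, so counting error is large for most genes. If reads were not reduced to molecules, their counting error is understated.

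All tests used log2(value + 1) with a pseudocount of 1, and fold changes are on that scale, which understates the change of low genes. Genes with a value above 0 in at least 3 regions were kept, which removed 0 genes. A fixed list of X-inactivation and Y-linked genes was left out of every test and table (13 present), leaving 11114 genes. The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), IPF minus healthy over all 11 regions, with Benjamini-Hochberg adjustment and a threshold of 0.05. The sets of IPF regions were tested with the same method, second minus first. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 52 lists with at least 5 measured members; of 53 lists with 1050 members, 795 members were measured, 2 through a synonym, and the erythrocyte list (3 measured) was too short. Whole-gene coordinates come from RefSeq on GRCh38, in which 10946 symbols matched and 168 did not.

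The design, the lists, the rule for named genes and the alternatives, except those said to be added, were fixed before the data were examined. Named were, among genes past the threshold whose groups did not overlap and whose mean was at or above the median, the 12 with the largest rise (8 qualified) and the 12 with the largest fall, 16 fixed focal genes, the 2 to 4 members of each list with the smallest adjusted p, and, between the sets, the 5 largest differences in each direction without overlap and with a mean at or above the median. Genes whose presence varies between people are not named. The names of the splicing genes that fell are not reported here as a group.

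Alternatives were the pseudocount (0.1 and 10), a filter on low genes, quantile normalization, equal totals, the label number as a random block or as averages, each set alone, the replicate number as a block in regions 1 to 3 of each group, region weights, no trend, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, an estimated correlation or fry for lists, and each region left out in turn, 28 alternatives for genes and 24 for lists. Thinning healthy regions to IPF depth and leaving out IPF regions 1 and 2 were added after the data were seen, as were edgeR for the sets, the fit of regions 1 to 3 with no block and the comparison of each list with 10000 lists of genes matched on healthy level (a window of 51 genes; level from a pair of healthy regions and change against the remaining one, in rotation).

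The procedure was tested on simulated data. For IPF against healthy, limma recovered 3%, 49.3% and 84.8% of genes changed 2-, 4- and 8-fold among 11114 genes, with 4 false of 95 calls; edgeR had 11 false of 113. Between the sets, limma recovered 3%, 43.3% and 47%, with 0 false of 62 calls. Regions were simulated as independent, with an assumed dispersion and no change that follows a gene's level. The rates may differ in the real data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.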

Results

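Gene expression was measured in 11 small regions of human lung tissue, each captured from the ciliated epithelium that lines the distal bronchioles. Of these, 8 regions came from lungs with idiopathic pulmonary fibrosis (IPF), a progressive scarring disease of the lung, and 3 came from healthy lungs. The assay was GeoMx spatial profiling, in which barcoded oligonucleotide probes hybridised to RNA in a fixed tissue section are released by light from a chosen region and counted by sequencing. The series' design sets the IPF regions against the healthy ones, and its title names the loss of epithelial cells from distal bronchioles as the subject. The region labels also carry a number that is shared by all 3 healthy regions, by IPF regions 1 to 4 (the first set) and by IPF regions 5 to 8 (the second set). What that number marks is not stated. If it marks a person, regions of a set are not independent, all healthy regions come from 1 person, and p-values computed over regions are too small.

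The healthy regions were measured more deeply than the IPF regions. The reads recovered from the deposited values summed to 147893 ± 12740 per healthy region (SD, n = 3) and to 65105 ± 6952 per IPF region (SD, n = 8), a ratio of 2.27 (exact permutation test, two-sided p = 0.0121). Healthy totals ran from 133466 to 157596 and IPF totals from 54851 to 71922. The share of genes with 10 or more reads was 48.3% ± 5.94 (SD, n = 3) in healthy regions and 9.53% ± 2.32 (SD, n = 8) in IPF regions. Across genes, Pearson's r between pairs of regions was 0.642 to 0.704 among healthy regions and 0.333 to 0.467 among IPF regions. Genes are not independent replicates, and counting error lowers r at low depth. A chi-square of reads per degree of freedom, which allows for counting error, had a median of 1.49 among healthy pairs. It was 1.20 and 1.26 among IPF pairs of the same and of different label number. The lower r thus does not show that IPF regions differ more from each other. The change between groups followed a gene's level: the 2794 genes with the lowest healthy levels had a median log2 change of 0.16, and the 111 genes with the highest had one of -0.61.

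Between IPF and healthy regions, 112 of 11114 genes changed (limma, adjusted p under 0.05), of which 19 were higher and 93 lower in IPF. Among them were genes of secretory cells, motile cilia, basal cells, antigen presentation and immunoglobulins. In all 112 genes the change was at least 2-fold on the log2(value + 1) scale. All 8 IPF regions lay above all 3 healthy regions for 8 of the risen genes, and below them for 81 of the fallen genes. Over all genes, 3.55% had groups that did not overlap, where chance gives 1.21%. Other scalings gave a different split, with 24 higher and 24 lower after quantile normalization, and 29 higher and 37 lower after rescaling regions to equal totals, which moved the median of all genes from -0.04 to 0.10. The count was 41 without healthy region 1, 67 without healthy region 2 and 30 without healthy region 3, and p-values are too small if regions share a person.

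Secretory genes changed in opposite directions. SCGB1A1, which encodes the main secreted protein of club cells (chromosome 11, 62419033 to 62423195 in GRCh38), fell from a value of 5500 ± 318 in healthy regions (SD, n = 3) to 203 ± 177 in IPF regions (SD, n = 8), a log2 change of -5.43 ± 0.70 (SE, limma adjusted p = 3.5e-07). It took 6.86% of reads in healthy regions and 0.273% in IPF regions. MUC5B, a gel-forming airway mucin (chromosome 11, 1223066 to 1262172), rose from 11.1 ± 7.79 to 114 ± 91.1, a log2 change of 3.03 ± 0.40 (adjusted p = 3.5e-07), and was higher in every IPF region than in any healthy region. BPIFB1, a secreted airway defence protein, rose by 3.38 ± 0.60 (SE) on the log2 scale, from 43.4 to 421. LCN2, an iron-scavenging defence protein, rose by 2.16 ± 0.41 (SE), from 8.83 to 50.4. In IPF regions 1 and 2, LCN2 was at 9.87 and 8.64 (healthy up to 14.3) and BPIFB1 at 40.7 and 55.5 (healthy up to 76.2). MGP, an inhibitor of calcification, fell by 1.80 ± 0.33 (SE) on the log2 scale, and lay lower in every IPF region than in any healthy region. Of 18 measured members of the club and secretory list, 2 rose and 4 fell over all genes tested, and 3 rose and 4 fell when adjusted over the list alone; the list as a whole was not called (camera, adjusted p = 0.281). Of 17 goblet cell and mucin genes, only MUC5B rose over all genes tested, and 2 rose and 1 fell when adjusted over the list alone (list adjusted p = 0.0761). MUC4, a membrane-bound mucin, had a log2 change of 1.06 with an adjusted p of 0.0653. P-values over regions are too small if regions share a person.

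Without healthy region 2, BPIFB1 had a log2 change of 2.11 (adjusted p = 0.230) and LCN2 one of 1.61 (adjusted p = 0.0521); LCN2 was also not called with the first IPF set alone (1.76, adjusted p = 0.0603) or with no mean-variance trend in limma (adjusted p = 0.0909). SCGB1A1 was not called with regions averaged per label number (-5.43, adjusted p = 0.123) or with only regions 1 to 3 of each group (-5.35, adjusted p = 0.0780; 0.185 with region numbers as blocks), and its adjusted p was under 0.05 in 26 of 28 alternatives. BPIFB1 (2.23, adjusted p = 0.185) and LCN2 (1.32, 0.325) were also not called with only regions 1 to 3 of each group. Both were called when region numbers were added as blocks (5.7e-05 and 0.0203). A healthy and an IPF region of the same number come from different lungs. Their deviations from the group means correlated at -0.0115, -0.0002 and 0.0072, against -0.0147 to 0.0177 in pairs of different number. The blocks thus had no basis in the data, and calls gained only with them, here and below, are no support.

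**Figure D1:**
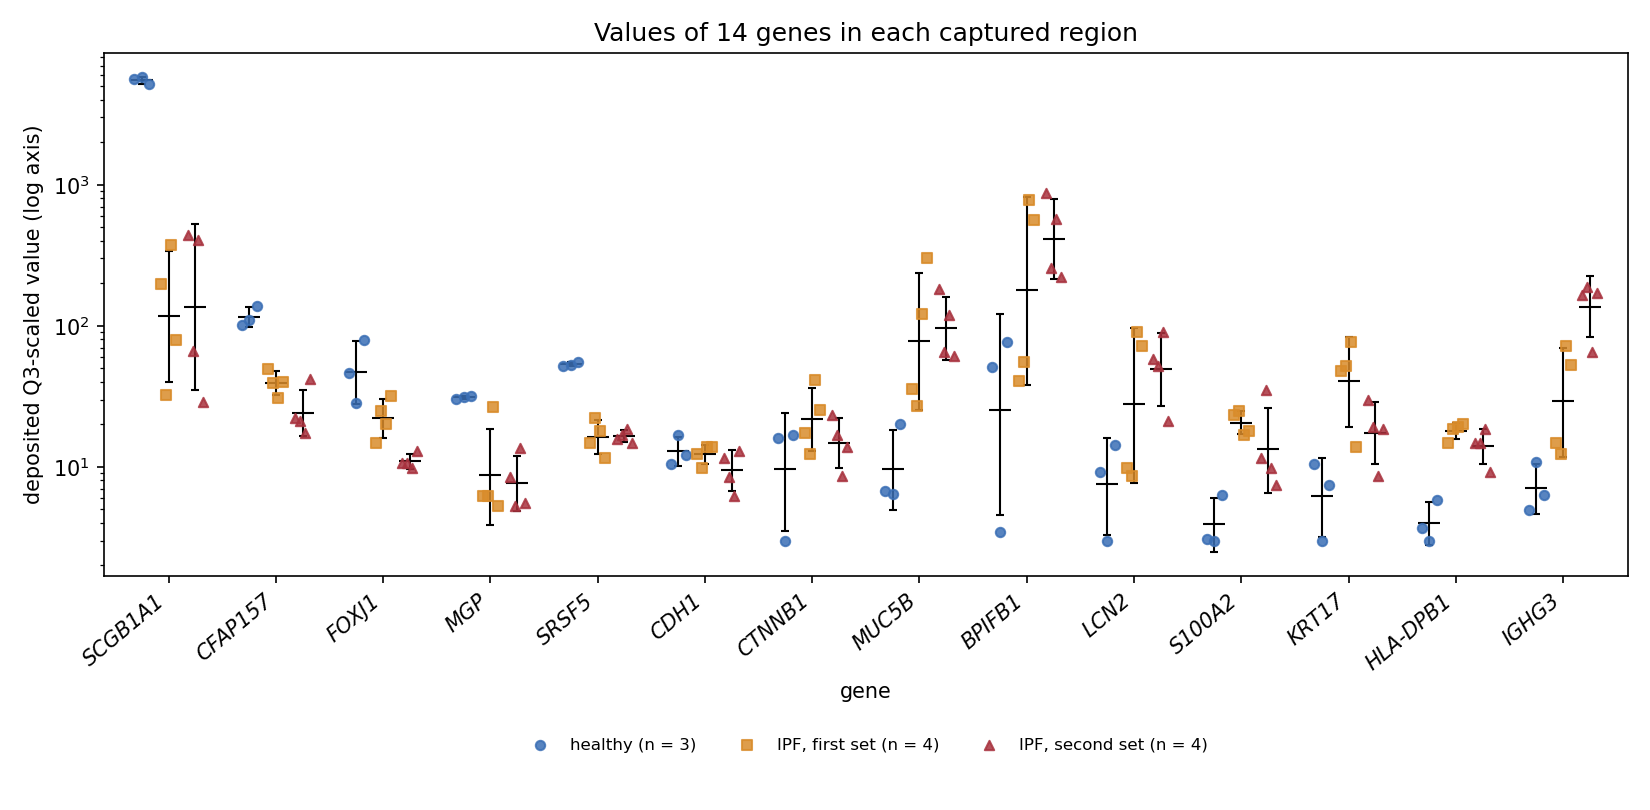
Deposited Q3-scaled values of 14 genes on a log axis, 1 point per captured region, for 3 healthy regions, IPF regions 1 to 4 (first set) and IPF regions 5 to 8 (second set); horizontal bars are means and whiskers SDs of log2(value + 1), transformed back. SCGB1A1 lies at 5500 ± 318 in healthy regions and at 203 ± 177 in IPF regions, while MUC5B lies at 11.1 ± 7.79 and 114 ± 91.1, and CDH1 overlaps between groups.

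Genes of motile cilia were lower in IPF regions. Of 34 measured genes of the axoneme list, 9 fell over all genes tested and 21 fell when adjusted over the list alone; all 34 had a log2 change below 0, with a median of -0.86 (camera with a preset correlation, adjusted p = 2.0e-21; adjusted p = 0.103 with an estimated correlation). CFAP157, a protein of motile cilia (chromosome 9, 127706988 to 127716002), fell from 117 ± 19.0 (SD, n = 3) to 32.8 ± 11.6 (SD, n = 8), a log2 change of -1.87 ± 0.32 (SE, adjusted p = 2.7e-04). CCDC40, needed to assemble the axoneme, fell by 1.69 ± 0.33 (SE) on the log2 scale. DNAAF1, an assembly factor of dynein arms, fell by 1.57 ± 0.30 (SE). TEKT1, a filament protein of the axoneme, fell by 1.34 ± 0.33 (SE). FOXJ1, the transcription factor that drives motile ciliogenesis, fell by 1.53 ± 0.32 (SE), from 51.1 to 16.9 (adjusted p = 0.00223). It was the only one of 14 ciliogenesis regulators that fell, and that list had a median of -0.27 (adjusted p = 0.0295; adjusted p = 0.236 with an estimated correlation), with IFT57, a protein of intraflagellar transport, at -0.65 and an adjusted p of 0.432. Regions had been chosen as ciliated. Genes of the same healthy level as the axoneme genes had a median log2 change of -0.49 (95% range of 10000 lists -0.60 to -0.36). The axoneme genes computed the same way had one of -0.87. The genes of each matched list were drawn independently, while the axoneme genes had an estimated correlation of 0.26. Such ranges, here and below, are too narrow for lists whose genes move together. Without healthy region 3 the calls of CCDC40 (log2 change -1.51, adjusted p = 0.0677), DNAAF1 (-1.39, adjusted p = 0.0513), FOXJ1 (-1.16, adjusted p = 0.189) and TEKT1 (-0.98, adjusted p = 0.570) were lost, and TEKT1 was also lost without healthy region 1 (-1.37, adjusted p = 0.148) and after quantile normalization (-1.11, adjusted p = 0.150) or rescaling to equal totals (-1.18, adjusted p = 0.0927). FOXJ1 was not called with the first IPF set alone (-1.06, adjusted p = 0.149), nor TEKT1 with the second (-1.28, adjusted p = 0.0594). In regions 1 to 3 of each group, FOXJ1 (-1.23, adjusted p = 0.0983) and DNAAF1 (-1.32, 0.0567) were not called. Both were called when region numbers were added as blocks (0.0428 and 0.0319). Calls ended with no mean-variance trend were those of CCDC40 (0.0654), DNAAF1 (0.0626), FOXJ1 (0.106) and TEKT1 (0.194), and p-values are too small if regions share a person.

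Other genes with the largest falls were RP1, a microtubule-associated protein, with a log2 change of -1.97 ± 0.36 (SE), VWA3B with -1.83 ± 0.35 (SE), PRRT1B with -1.77 ± 0.37 (SE), MS4A8 with -1.70 ± 0.31 (SE), UBXN11 with -1.70 ± 0.31 (SE), METTL7A with -1.67 ± 0.30 (SE), SRSF5, a splicing factor, with -1.65 ± 0.29 (SE), and CRACR2B with -1.64 ± 0.32 (SE). Each lay lower in all 8 IPF regions than in all 3 healthy regions. SRSF5 fell from 53.4 ± 1.92 (SD, n = 3) to 16.6 ± 3.13 (SD, n = 8). VWA3B was not called without healthy region 3 (log2 change -1.68, adjusted p = 0.0668), and PRRT1B was not called without healthy region 1 (adjusted p = 0.0616) or region 3 (adjusted p = 0.0513). These p-values are too small if regions share a person.

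Basal cell genes were higher in IPF regions. All 13 measured members of the basal list had a log2 change above 0, with a median of 0.84 (camera, adjusted p = 3.5e-10; adjusted p = 0.103 with an estimated correlation); 3 rose over all genes tested and 7 when adjusted over the list alone. S100A2, a calcium-binding protein of basal cells (chromosome 1, 153561108 to 153565844), rose from 4.13 ± 1.92 (SD, n = 3) to 18.4 ± 9.10 (SD, n = 8), a log2 change of 1.83 ± 0.33 (SE, adjusted p = 3.7e-04). KRT17, a keratin of basal and injured epithelium, rose by 1.93 ± 0.36 (SE) on the log2 scale, from 6.95 to 33.2. KRT5, the defining keratin of basal cells, rose by 1.70 ± 0.40 (SE), from 7.90 to 35.6. The list of aberrant basaloid cells of fibrotic lung, which shares KRT17, was not called (median -0.06, adjusted p = 0.435), and its member MMP7, a matrix protease, had a log2 change of 0.86 ± 0.42 (SE) with an adjusted p of 0.508. MMP7 was at 4.94 and 6.17 in IPF regions 1 and 2 and at 13.9 to 104 in the others; it was called without those 2 regions (1.52, adjusted p = 0.00936) and with edgeR (adjusted p = 0.0228). KRT5 was not called without healthy region 1 (log2 change 1.56, adjusted p = 0.159) or healthy region 2 (1.59, adjusted p = 0.0547), nor with the second IPF set alone (1.20, adjusted p = 0.304), without IPF regions 1 and 2 (1.43, adjusted p = 0.0695) or with a pseudocount of 0.1 (adjusted p = 0.0632). With no mean-variance trend neither KRT5 (adjusted p = 0.221) nor KRT17 (adjusted p = 0.0769) was called, and p-values are too small if regions share a person.

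Antigen presentation genes were higher in IPF regions. The list of MHC class II genes had a median log2 change of 1.06 over 10 measured members, of which 3 rose over all genes tested and 8 when adjusted over the list alone (camera, adjusted p = 3.3e-14; adjusted p = 0.103 with an estimated correlation). HLA-DPB1 rose from 4.16 ± 1.48 (SD, n = 3) to 16.2 ± 3.55 (SD, n = 8), a log2 change of 1.75 ± 0.31 (SE, adjusted p = 2.7e-04). HLA-DQA1 rose by 2.08 ± 0.37 (SE) on the log2 scale, and HLA-DQB1 by 1.31 ± 0.33 (SE). All 12 genes of MHC class I and peptide loading had a log2 change above 0, with a median of 0.60 (adjusted p = 4.9e-07; adjusted p = 0.211 with an estimated correlation). Of these, HLA-C rose by 1.35 ± 0.32 (SE), from 15.8 to 45.9. HLA genes differ between people and resemble each other, so a probe can read them unequally or read several. The interferon response list had 21 of 23 members above 0 and a median of 0.60 (adjusted p = 1.1e-07; adjusted p = 0.258 with an estimated correlation), with no member called over all genes tested and 2 risen when adjusted over the list alone. Its call was lost with the second IPF set alone (median 0.22, adjusted p = 0.0769), as were those of HLA-DQA1 (1.56, adjusted p = 0.0594), HLA-C (0.84, adjusted p = 0.150) and HLA-DQB1 (0.88, adjusted p = 0.331). HLA-C was not called without healthy region 1, 2 or 3 (adjusted p = 0.0616, 0.152 and 0.0998), nor HLA-DQB1 without healthy region 2 (0.344), healthy region 3 (0.115), IPF region 3 (0.0560) or IPF regions 1 and 2 (0.0779). With no mean-variance trend HLA-C (0.167) and HLA-DQB1 (0.227) were not called, and p-values are too small if regions share a person.

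Of the immunoglobulin genes, 6 rose in IPF regions. IGHA1 (log2 change 0.73 ± 0.37 SE, adjusted p = 0.552) and IGHM (0.78 ± 0.39 SE, adjusted p = 0.546), both on the B and plasma cell list, were not called. IGHG3 rose from 7.38 ± 3.09 (SD, n = 3) to 92.8 ± 71.6 (SD, n = 8), a log2 change of 3.01 ± 0.43 (SE, adjusted p = 1.9e-06), and IGHG2 rose by 2.83 ± 0.40 (SE) on the log2 scale, from 5.27 to 57.1. Both lie in the heavy chain locus on chromosome 14 (IGHG3 at 105765914 to 105771405). IGHG4 rose by 2.49 ± 0.49 (SE), IGKC, the kappa light chain, by 2.25 ± 0.44 (SE), IGHG1 by 2.16 ± 0.40 (SE) and IGLL5 by 1.66 ± 0.37 (SE). IPF regions 1 and 2 lay near the healthy values in IGHG4 (12.3 and 2.47, healthy 5.82 to 11.4), IGKC (9.87 and 8.64, healthy 4.23 to 17.8), IGHG1 (9.87 and 4.94, healthy 4.76 to 8.39) and IGLL5 (6.17 and 3.70, healthy 2.47 to 5.82). The IGHG genes are near-identical, so a probe for 1 of them can also bind RNA of the others. The B and plasma cell list had a median of 0.27, with 2 of 11 members risen (adjusted p = 5.8e-04; adjusted p = 0.170 with an estimated correlation). With the first IPF set alone, this list (median 0.06, adjusted p = 0.108), IGHG1 (1.28, adjusted p = 0.179), IGHG4 (1.07, adjusted p = 0.420), IGKC (0.98, adjusted p = 0.341) and IGLL5 (0.85, adjusted p = 0.5001) were not called. IGKC was not called without healthy region 3 (1.82, adjusted p = 0.0729), nor IGLL5 without healthy region 1 (1.35, adjusted p = 0.216). With no mean-variance trend IGHG4 (0.118), IGKC (0.106), IGLL5 (0.160) and IGHG1 (0.0769) were not called. With only regions 1 to 3 of each group, which leaves out IPF regions 4 to 8, IGHG4 (0.60, adjusted p = 0.732), IGKC (0.67, 0.598), IGLL5 (0.81, 0.552), IGHG1 (0.83, 0.491) and the B and plasma cell list (0.212) were not called. With region numbers as blocks in that fit they were not called either (0.580, 0.495, 0.476, 0.364 and 0.156). IGHG3 (1.63, adjusted p = 0.0627) and IGHG2 (1.56, 0.0582) were also not called with only those regions. With the blocks IGHG3 and IGHG2 were called (0.00124 and 0.00556), and p-values are too small if regions share a person.

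SAT1, a polyamine-acetylating enzyme (X chromosome), was the remaining gene named for its rise, with a log2 change of 1.20 ± 0.32 (SE), from 23.3 to 56.9 (adjusted p = 0.0402). Its call was lost on leaving out any healthy region (adjusted p = 0.226, 0.325 and 0.146) or IPF region 3 (0.0595), 4 (0.0770) or 6 (0.0660), and it was not called with the second IPF set alone (0.87, adjusted p = 0.150), with regions averaged per label number (0.179), with no mean-variance trend (0.221) or with a pseudocount of 0.1 (0.0554). These p-values are too small if regions share a person.

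Genes of junctions between epithelial cells, and genes that attach cells to the matrix, did not pass the test. No member of the desmosome (9 measured), adherens junction (10), tight junction (16), hemidesmosome (17), integrin (11) or focal adhesion (22) lists was called over all genes tested; adjusted over the list alone, 1 tight junction gene and 2 hemidesmosome genes fell. Median log2 changes were -0.01 for the desmosome list (adjusted p = 0.931), 0.14 for adherens junctions (0.762), -0.37 for tight junctions (0.0774), -0.05 for the hemidesmosome list (0.871), -0.10 for integrins, whose mean was 0.01 (0.722), and -0.08 for focal adhesion (0.878). Against genes of their healthy level, adherens junction (0.03 against -0.43 to 0.02) and focal adhesion genes (-0.05 against -0.41 to -0.09) lay above their ranges. The other lists of this paragraph lay within theirs, and 19 of 52 lists in all lay above. CDH1, the epithelial cadherin, had a value of 13.1 ± 3.26 in healthy regions (SD, n = 3) and 11.1 ± 2.73 in IPF regions (SD, n = 8), a log2 change of -0.24 ± 0.31 (SE, adjusted p = 0.900). CTNNB1, the beta-catenin gene, had a log2 change of 0.83 ± 0.34 (SE) with an adjusted p of 0.357, and JUP, the plakoglobin gene, one of -0.79 ± 0.32 (SE) with an adjusted p of 0.357. CTNNB1 was at 2.96 in healthy region 2 and at 16.0 and 16.9 in healthy regions 1 and 3, against 8.64 to 41.3 in IPF regions. Healthy region 2 held the same value, 6 reads, for CTNNA1 (13.6 and 15.9 in healthy regions 1 and 3), ATP1B1 (27.2 and 31.7), IGFBP7 (16.7 and 31.7), LCN2 (9.26 and 14.3) and KRT17 (10.5 and 7.41). It also held it for S100A2 (3.09 and 6.35) and HLA-DPB1 (3.70 and 5.82), which were low in all healthy regions. Why these genes share a value was not tested, and it raises the log2 changes of those higher in the other healthy regions. Over 28 alternatives the log2 change of CTNNB1 ran from 0.12 to 1.21. CTNNA1 had 0.41 ± 0.32, DSP 0.25 ± 0.34, EPCAM -0.39 ± 0.34 and TJP1 0.00 ± 0.43 (SE). In simulated data for this comparison, 3% of genes changed 2-fold and 49.3% of those changed 4-fold were recovered, so a 2-fold change of a junction gene was mostly not detectable at this depth. TJP1 and DSP had changes below 0 with the second IPF set alone (-0.22 and -0.04), and CTNNA1 had one of -0.25 without healthy region 2; p-values are too small if regions share a person.

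Of 52 lists tested, 11 were higher and 6 lower in IPF with the preset correlation of 0.01, and 0 passed with an estimated correlation, where 11 had an unadjusted p under 0.05; fry called 6. Ribosomal protein genes had a median log2 change of -0.69, with 1 of 34 fallen over all genes tested, RPS15 with -1.15, and 18 when adjusted over the list alone (adjusted p = 1.3e-12; adjusted p = 0.219 with an estimated correlation). Genes of their healthy level moved alike, with a median of -0.57 (95% range -0.70 to -0.43) against -0.65 for the ribosomal genes. The same held for heat shock chaperones (-0.46 against a range of -0.58 to -0.15; list adjusted p = 0.0220; adjusted p = 0.170 with an estimated correlation) and oxidative phosphorylation (-0.31 against -0.49 to -0.22; list adjusted p = 0.0199; adjusted p = 0.258 with an estimated correlation). Xenobiotic metabolism genes lay below their level-matched range (-0.58 against -0.48 to -0.10), with 3 of 16 fallen over all genes tested, and 6 fallen and 1 risen when adjusted over the list alone (adjusted p = 4.1e-05; adjusted p = 0.103 with an estimated correlation). These were ALDH3B1 with -1.42, CYP4B1 with -1.31 and ALDH1A1 with -1.17, enzymes that oxidise aldehydes or foreign compounds. FABP5 and FABP6, carriers of fatty acids and bile acids, fell by 1.41 and 1.26 on the log2 scale. RPS15, ALDH1A1, CYP4B1, FABP5 and FABP6 were not called without healthy region 1 (adjusted p = 0.233, 0.285, 0.102, 0.186 and 0.0790), RPS15 and FABP6 were not called without healthy region 2 (0.124 and 0.302), and RPS15, ALDH3B1, ALDH1A1, CYP4B1, FABP5 and FABP6 were not called without healthy region 3 (0.153, 0.115, 0.387, 0.0839, 0.0912 and 0.387). After quantile normalization RPS15 (0.288), ALDH3B1 (0.0655), CYP4B1 (0.0994), ALDH1A1 (0.213), FABP5 (0.0969) and FABP6 (0.136) were not called, nor were the heat shock (0.176), oxidative phosphorylation (0.110) and ciliogenesis (0.116) lists. With regions averaged per label number CYP4B1 (0.0652) and RPS15 (0.104) were not called. No mean-variance trend ended the calls of RPS15 (0.227), ALDH3B1 (0.0909), CYP4B1 (0.118), ALDH1A1 (0.194), FABP5 (0.118) and FABP6 (0.167). FABP6 was not called with the first IPF set alone (0.0521), nor ALDH1A1 with that set (0.117) or with only regions 1 to 3 of each group (0.134; 0.0914 with region numbers as blocks). FABP5 (0.0617) and FABP6 (0.0845) were also not called with only those regions, but were called with the blocks (0.0373 and 0.0270). RPS15 and FABP6 were not called with the second set alone (0.0910 and 0.0602) or after thinning (0.0964 and 0.133). Equal totals ended the calls of ALDH1A1, RPS15 and FABP6 (0.111, 0.107 and 0.124). RPS15 was not called without IPF region 6 (0.0733), nor FABP6 without IPF region 1 (0.0636) or with a pseudocount of 0.1 (0.0623), and p-values are too small if regions share a person.

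Endothelial, fibroblast and macrophage lists were higher in IPF. Endothelial genes had a median of 0.48 (adjusted p = 0.0178; adjusted p = 0.170 with an estimated correlation), fibroblast and collagen genes one of 0.31 (0.0173; adjusted p = 0.258 with an estimated correlation) and macrophage genes one of 0.21 (0.0303; adjusted p = 0.369 with an estimated correlation), with no member called over all genes tested and, adjusted over the list alone, 0, 1 and 1 risen. The fry test called none of the 3 (adjusted p = 0.104, 0.283 and 0.356). The lists of smooth muscle (median -0.07, adjusted p = 0.399), T and NK cells (-0.02, 0.839), neutrophils and mast cells (0.33, 0.443) and alveolar type 1 (0.13, 0.557) and type 2 cells (0.23, 0.187) were not called. The macrophage genes moved like genes of their healthy level (0.20 against a range of -0.09 to 0.26), while the endothelial (0.49 against -0.07 to 0.39) and fibroblast genes (0.28 against -0.10 to 0.25) lay above their ranges. Lying above was common, with 19 of 52 lists above and 4 below their ranges, lists that were not called among them. It does not set the endothelial and fibroblast genes apart. COL1A1 had a value of 3.23 ± 0.66 in healthy (SD, n = 3) and 5.20 ± 2.59 in IPF regions (SD, n = 8), with an adjusted p of 0.842, and CD68 had an adjusted p of 0.711. The median member had 4.13 to 4.63 reads per IPF region, near the median of all genes. Antimicrobial genes (median 0.26, adjusted p = 0.00270; adjusted p = 0.170 with an estimated correlation), p53 targets (0.26, adjusted p = 0.0102; adjusted p = 0.103 with an estimated correlation) and matrix proteases (0.16, adjusted p = 0.0416; adjusted p = 0.236 with an estimated correlation) were the others called higher. IGFBP5, which binds insulin-like growth factors and is in the p53 list, fell from 15.3 to 5.45 (adjusted p = 0.0251), against the direction of the list, and was not called without healthy region 1 (adjusted p = 0.248) or region 3 (0.415), after quantile normalization (0.0998), equal totals (0.0905) or thinning (0.0517), with the first IPF set alone (0.0668), with a pseudocount of 0.1 (0.0523) or with no mean-variance trend (0.139). In regions 1 to 3 of each group IGFBP5 was called only with region numbers as blocks (0.0427, against 0.136 without). Without healthy region 3, the endothelial (adjusted p = 0.125), fibroblast (0.145), macrophage (0.145), matrix protease (0.0673), heat shock (0.139), oxidative phosphorylation (0.107) and ciliogenesis (0.289) lists were not called, and without healthy region 2 the matrix protease (0.0955) and p53 (0.0504) lists were not. Without IPF region 3 the ciliogenesis (0.0833), macrophage (0.0833) and matrix protease (0.130) lists were not called either. The macrophage list was also not called without IPF region 1 (0.0625) or 5 (0.0828) or after thinning (0.0637), nor was the matrix protease list without IPF region 4 (0.0954) or 5 (0.0510). With only regions 1 to 3 of each group the fibroblast (0.215), heat shock (0.0936) and antimicrobial (0.277) lists were not called, nor with region numbers as blocks in that fit (0.198, 0.122 and 0.0607). The matrix protease list had a median of -0.03 in that fit and was called only with the blocks (adjusted p = 0.0334, against 0.0668 without). Leaving out the lowest genes ended the calls of the macrophage (0.118) and oxidative phosphorylation (0.0722) lists, and leaving out IPF regions 1 and 2 those of the oxidative phosphorylation (0.0884) and ciliogenesis (0.0524) lists. With the first IPF set alone the fibroblast (median 0.14, adjusted p = 0.115), macrophage (0.11, adjusted p = 0.0614) and heat shock (-0.32, adjusted p = 0.0950) lists were not called. With the second set alone the macrophage (0.27), p53 (0.24) and oxidative phosphorylation (-0.23) lists (adjusted p = 0.0769 each), the ciliogenesis list (-0.15, adjusted p = 0.0888) and the matrix protease list (0.12, adjusted p = 0.184) were not called, and p-values are too small if regions share a person.

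**Figure D2:**
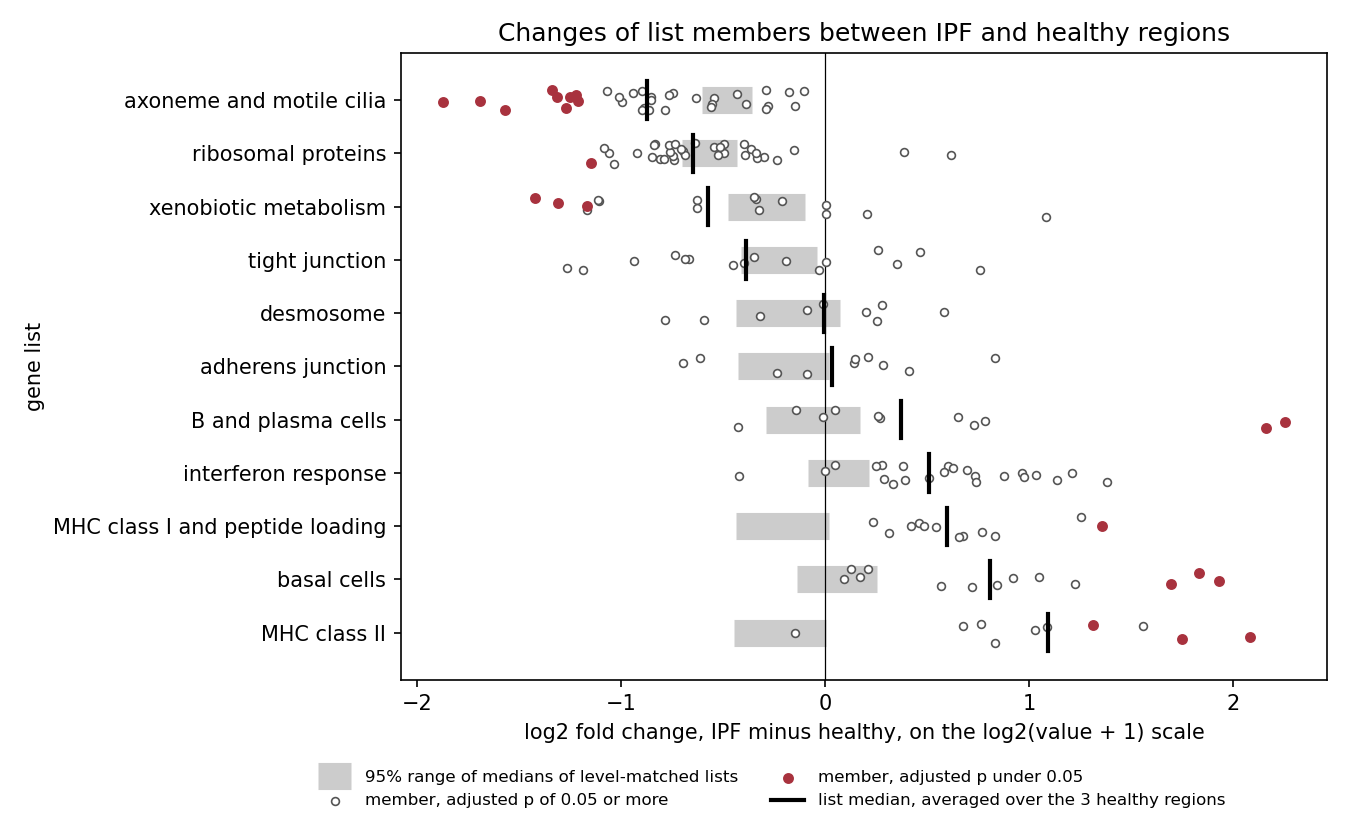
Log2 fold changes (IPF minus healthy, log2(value + 1) scale) of the measured members of 11 gene lists; filled points passed the test over all genes, black bars are list medians averaged over the 3 healthy regions, and grey bands are the 95% range of medians of 10000 lists matched on healthy level. The axoneme median of -0.87 lies below its band of -0.60 to -0.36, the MHC class II median of 1.09 lies above its band, and the ribosomal median of -0.65 lies within its band.

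The sets of IPF regions that share a label number were compared with each other to see how far IPF regions of different number differ. Immunoglobulin genes were higher in the second set. IGHG4 was at 27.8 ± 23.9 in the first set and 135 ± 38.7 in the second (SD, n = 4 each), a log2 difference of 2.84 ± 0.36 (SE, limma adjusted p = 6.2e-10). IGKC differed by 2.56 ± 0.34 (SE), from 21.6 to 115. IGHG3 lay at 38.0 and 148 in the sets, and IGHG2, IGHG1 and IGLL5 differed by 2.18, 1.77 and 1.63 on the log2 scale. DNHD1 was also higher, by 1.83, and SFTPC, the surfactant protein C gene, by 1.54, with overlapping sets and a value of 102 in IPF region 7 against 2.12 to 21.3 in the other regions of the second set. Lower in the second set were EGR1, an immediate early transcription factor, with -1.97, B2M, the light chain of MHC class I, with -1.69, IFITM3, an interferon-induced membrane protein, with -1.61, SCO2, a copper chaperone of the respiratory chain, with -1.35, and SOD2, a mitochondrial superoxide dismutase, with -1.30. MMP1, a collagenase whose mean lay below the median gene, was chosen after its values were seen; it was at 23.4 ± 27.8 in the first set and 2.63 ± 0.45 in the second (SD, n = 4 each, adjusted p = 0.00177), and was not called without IPF region 2 (0.327) or 3 (0.591). In all, 20 genes differed, 10 in each direction, and 632 had an unadjusted p under 0.05, while edgeR called 25, of which 6 were higher and 19 lower in the second set; 13 of the 20 had sets that did not overlap. IGHG4, IGKC, IGHG2 and B2M kept their calls on leaving out any 1 region, but IGHG4 differed by 2.04 without IPF region 2. Without regions 1 and 2 limma called none of them, with IGHG4 at 1.41 (adjusted p = 0.569), IGKC at 1.67 (0.228), IGHG2 at 1.47 (0.298) and B2M at -1.42 (0.228). In that fit, of 2 regions against 4, edgeR called 13 genes, but not IGHG4 (0.248) or IGHG2 (0.136). Among the 13 were IGKC (0.0452), B2M (0.00752), SOD2 (0.00528), SFTPC (0.00122) and MMP1 (1.0e-12). MMP1 was at 63.5 in IPF region 3 and 4.23 in region 4, against 2.12 to 3.17 in the second set. Its difference, like that of SFTPC with 102 in IPF region 7, rested largely on 1 region. Without IPF region 7, SFTPC differed by 0.65 (adjusted p = 0.954), and it was not called without region 1 (0.583), 2 (0.379) or 8 (0.241). Without region 2, IGHG3 (0.0854), IGHG1 (0.379), IGLL5 (0.171) and IFITM3 (0.121) were not called, nor EGR1 without region 1 (0.387). DNHD1 was not called without region 2 (0.240), 3 (0.0915), 5 (0.472), 6 (0.204) or 7 (0.212). SCO2 was not called without region 1 (0.512), 2 (0.416), 6 (0.316) or 8 (0.251), nor SOD2 without region 1 (0.511), 3 (0.432), 5 (0.155), 6 (0.182) or 8 (0.0872). With edgeR, IGLL5 (0.0518) and IGHG1 (0.0711) were not called. A pseudocount of 0.1 ended the calls of SFTPC (0.541), DNHD1 (0.0971), SCO2 (0.0847) and SOD2 (0.0911). So did leaving out the lowest genes, with SFTPC (0.390), DNHD1 (0.0812), SCO2 (0.0952) and SOD2 (0.0971). SCO2 was also not called with a pseudocount of 10 (0.0631), nor DNHD1 after quantile normalization (0.0515). IGHG genes are near-identical, so a probe can bind RNA of several, and p-values are too small if regions of a set share a person.

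Of the lists, 2 were higher and 9 lower in the second set (camera). The median difference was -0.77 for MHC class II (adjusted p = 4.1e-09; adjusted p = 0.208 with an estimated correlation), -0.74 for the interferon response (1.6e-11; adjusted p = 0.338 with an estimated correlation) and 0.62 for B and plasma cells (1.8e-06; adjusted p = 0.140 with an estimated correlation). With an estimated correlation 0 lists passed, and 7 had an unadjusted p under 0.05; fry called 0. Without IPF regions 1 and 2, the IPF regions with the fewest reads, limma called 0 genes, with 598 at an unadjusted p under 0.05, and edgeR called 13. The count was 11 without IPF region 1, 6 without region 2, 32 without region 3 and 12 without region 6, and p-values are too small if regions of a set share a person.

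**Figure D3:**
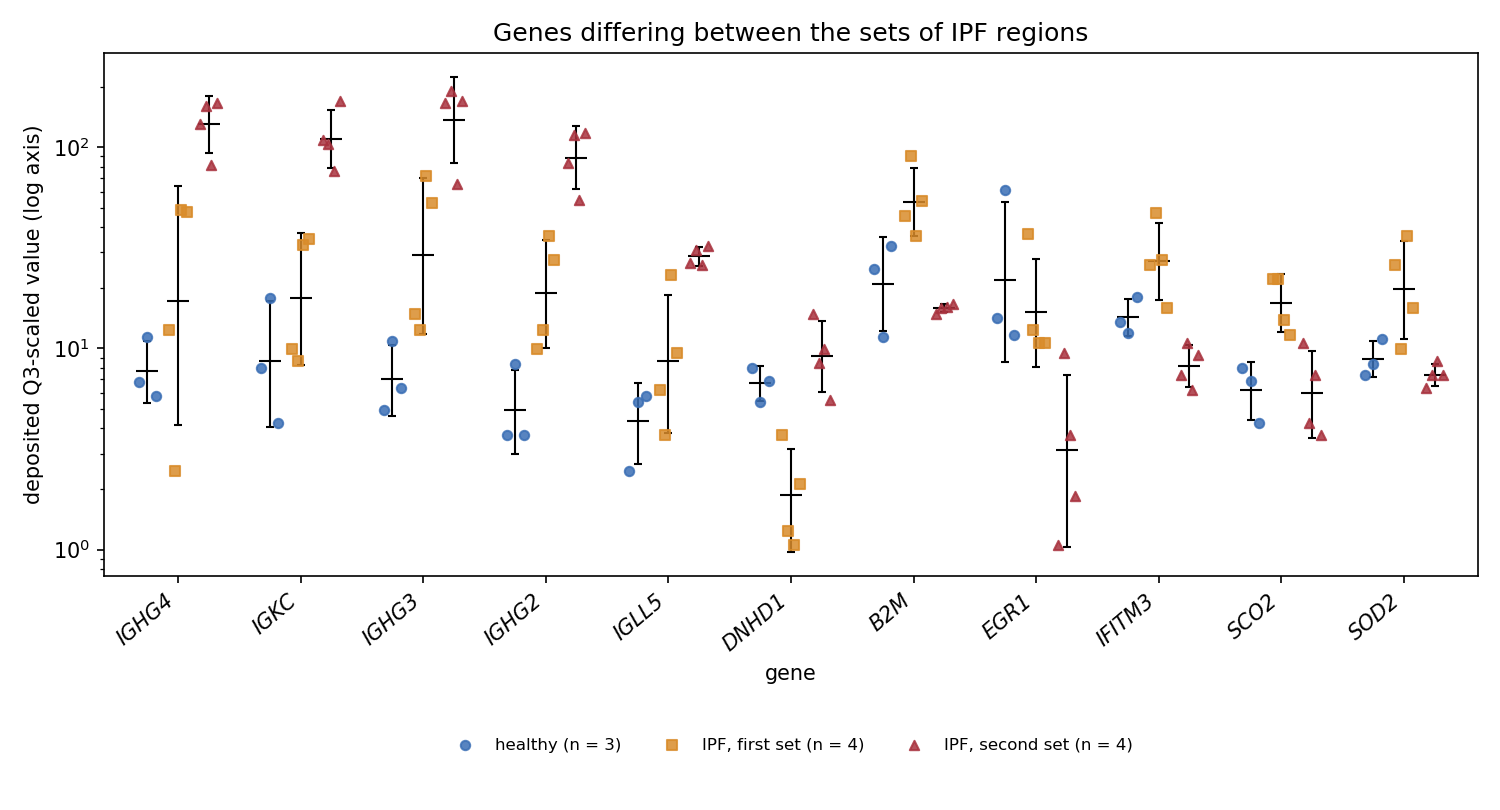
Deposited Q3-scaled values of 11 genes on a log axis, 1 point per region, for 3 healthy regions and the sets of 4 IPF regions each; horizontal bars are means and whiskers SDs of log2(value + 1), transformed back. IGHG4 lies at 27.8 ± 23.9 in the first set and 135 ± 38.7 in the second, and B2M at 56.4 ± 23.6 and 15.8 ± 0.77.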

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

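In this part, the tests of other cell types, of shared IGHG signal and of T and NK cells were chosen after the result was seen. The same holds for those of the share of secretory cells and of weaker signal on the secretory genes. Also chosen after the result were edgeR for the sets and the fits without IPF regions 1 and 2. The tests by level-matched lists, thinning, plasma cell genes and the share of SCGB1A1 were chosen after the pattern was seen. Their bounds were written before their values. Of 100 splits of the 11 regions into groups of 3 and 8, only the real one, 1 split, gave as many changed genes (112, highest other 12). That argues against chance for the gene count if regions are independent, though no share below 1 in 100 could be reached. Only the real split gave as many lists (17), but another gave 15, so chance is not excluded for the list count. If the label number marks a person, the regions form 3 sets, too few for such splits, and with an estimated correlation 0 lists passed. The splits do not separate disease from depth, tissue block or person, which follow the groups.

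Cilia genes were lower in IPF regions, which had been chosen as ciliated. The axoneme list's median of -0.87 was below all 10000 level-matched lists (median -0.49), although those lists were also below 0. Their genes were drawn independently, while the axoneme genes had an estimated correlation of 0.26. Such lists vary too little, so weaker signal over background is not excluded as the whole source. Part of the fall may be shared with other genes of that level. With healthy regions thinned to IPF depth the median was -0.90, so fewer reads drawn at the same shares did not give the fall. Thinning could move these genes little, since their median member had 31 reads per healthy region. It keeps each gene's share of reads, so it cannot test a depth effect that acts through background. Other captured cells stay open, since the highest of 5 medians, 0.48 for endothelial genes, lay between the bounds of 0.3 and 1, in genes near 4.13 reads. Fewer ciliated cells or lower expression per cell was not tested, and neither was a difference between tissue blocks.

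Several immunoglobulin genes were higher in IPF regions, and higher in the second set than in the first. Signal shared among IGHG genes through probe binding would not cover IGKC, which does not resemble them and had a log2 change of 2.25 ± 0.44 (SE). Its rise was already part of the pattern, so IGKC is no separate test, and sharing among the IGHG genes stays open. Plasma cells or their RNA stay open, since JCHAIN (0.65), DERL3 (-0.01), TNFRSF17 (0.26) and POU2AF1 (0.05) had a median of 0.15, between the bounds of 0 and 0.5. Lymphocytes of all kinds stay open too, since the T and NK median of -0.021 comes from genes with a median of 4.06 reads, near the floor; the requirement of 10 reads was added after the value was seen. A difference between people, which the label number may mark, was not tested.

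SCGB1A1 and SCGB3A2 were lower while BPIFB1, MUC5B and LCN2 were higher in IPF regions; SCGB3A2 (-3.25) was chosen after its values were seen. A smaller share of all secretory cells, or weaker signal over background, was set against MUC5B, a focal gene fixed before its direction was known. Its log2 change of 3.03 ± 0.40 (SE) shows that not all secretory genes fell. That rise is part of the pattern and was seen before the test was chosen, so it is no separate evidence. For the genes that fell both explanations stay open. The share of SCGB1A1 in healthy reads, 6.86%, is too small to give the rises of BPIFB1, MUC5B and LCN2. Its removal could move them little, so the values at equal totals are no separate test. Their median rise was 3.09 without SCGB1A1 and SCGB3A1 and 3.19 with them, both at equal totals, and 3.03 as deposited. Which secretory cell types changed was not tested, and neither was a difference between people. Without healthy region 2, BPIFB1 (2.11) and LCN2 (1.61) were not called.

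Of 62 measures in the 8 IPF regions, 3 had a region far from the others, where chance gives about 1 in 20. FABP6 was lowest in IPF region 1 (value 2.47, others 4.94 to 7.41), with a gap of 0.607 of the range on the log2 scale. HLA-DPB1 was lowest in IPF region 8 (9.26, others 14.8 to 20.1), with a gap of 0.6, and KRT5 in IPF region 7 (2.47, others 21.2 to 80.2), with a gap of 0.588.

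The sets of IPF regions differed by the test of the difference itself, second minus first on the log2 scale, in IGHG4 (2.84), IGKC (2.56), IGHG3 (2.2), IGHG2 (2.18), DNHD1 (1.83), IGHG1 (1.77), IGLL5 (1.63), SFTPC (1.54, 0.65 without IPF region 7), EGR1 (-1.97), B2M (-1.69), IFITM3 (-1.61), SCO2 (-1.35) and SOD2 (-1.30). Lists that differed had medians of -0.77 (MHC class II), -0.74 (interferon response), -0.60 (MHC class I), -0.49 (immediate early genes), -0.37 (basal cells), -0.35 (epithelial keratins), -0.35 (complement), -0.25 (apoptosis), -0.13 (axoneme), 0.27 (ribosomal proteins) and 0.62 (B and plasma cells), but 0 lists passed with an estimated correlation (lowest adjusted p = 0.0832) or fry. Chance was not excluded for these counts. The list differences were not tested without IPF regions 1 and 2. Of 35 splits of the IPF regions into sets of 4, 2 gave as many genes (real 20, highest other 27, for regions 1, 2, 4 and 8 against the rest) and 4 gave as many lists (real 11, highest other 14).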

How the results depend on the processing

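Thinning, edgeR for the sets and the fits without IPF regions 1 and 2 were chosen after the result was seen. Of 1618 values of 58 named genes under 28 alternatives, 1425 kept their direction and side of the threshold, 145 lost the call, 16 gained it and 32 changed sign, none of them of a gene called between IPF and healthy regions. Of 407 values of 17 lists under 24 alternatives, 341 kept their call and 66 lost it. Of 210 values of 15 genes that differed between the sets, under 14 alternatives, 149 kept their call, 61 lost it and 0 changed sign. The filter on low values removed 0 genes, so leaving it out tested nothing. The cause of each difference below was not tested, except that leaving out regions leaves fewer. Depth limits the low genes, with a median of 6 reads per gene.

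Against 112 genes (19 higher, 93 lower, 112 at least 2-fold), a pseudocount of 10 gave 178, with 157 lower and 37 at least 2-fold. Quantile normalization gave 48, with 24 lower and 48 at least 2-fold, and equal totals gave 66, with 29 higher, 37 lower and 66 at least 2-fold. The label number as a random block gave 205 (42 higher, 163 lower, 197 at least 2-fold), with an estimated correlation of -0.07. Region weights gave 315 (73 higher, 242 lower, 268 at least 2-fold), and no trend gave 19 (7 higher, 12 lower, 19 at least 2-fold). edgeR gave 290 (80 higher, 210 lower, 275 at least 2-fold). Regions 1 to 3 of each group with region numbers as blocks gave 162 (50 higher, 112 lower), and the same regions with no block 79. Regions of the same number did not resemble each other, so the larger count is no support. DESeq2, with 2709 genes tested, gave 146 (29 higher, 117 lower), thinning 146 (45 higher, 101 lower) and leaving out IPF regions 1 and 2 148 (29 higher, 119 lower). Leaving out 1 region gave 30 to 126 genes, 12 to 25 higher, 14 to 104 lower and 30 to 126 at least 2-fold. Against 17 lists, an estimated correlation gave 0 (11 at an unadjusted p under 0.05), fry 6, and leaving out 1 region 11 to 19. Against 20 genes between the sets, 10 in each direction, edgeR gave 25 (6 higher, 19 lower), a pseudocount of 0.1 gave 12, leaving out the lowest genes 12, leaving out 1 region 6 to 32, and leaving out IPF regions 1 and 2 gave 0 with limma (598 at an unadjusted p under 0.05) and 13 with edgeR.

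Changes of sign between IPF and healthy regions were as follows. With a pseudocount of 0.1, TJP1 had -0.032 and SFTPC -0.049. With the first set alone, SFTPC had -0.74. With the second set alone, DSP had -0.036, TJP1 -0.22, DNHD1 0.40, B2M -0.38, IFITM3 -0.73, SCO2 -0.042 and SOD2 -0.23. With region numbers as blocks in regions 1 to 3 of each group, MMP7 had -0.11, COL1A1 -0.029 and SFTPC -0.80. IFITM3 had -0.0075 with region weights, SFTPC -0.12 with DESeq2, and TJP1 -0.13 after thinning. Without IPF regions 1 and 2, DSP had -0.053 and IFITM3 -0.31. Leaving out 1 region gave TJP1 -0.15 to 0.15, SFTPC -0.47 to 0.25, CTNNA1 -0.25 to 0.80 and IFITM3 -0.15 to 0.24.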

Other observations

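The tests of the splicing list and of PTBP1 were chosen after the result was seen. Some lists that were not called between IPF and healthy regions held genes that passed the test over all genes. FABP5 and FABP6 were the 2 of 18 fatty acid and lipid metabolism genes that fell (list median -0.15, camera adjusted p = 0.142), and the list, computed in rotation, had a median of -0.32 against a level-matched range of -0.30 to 0.05. CFLAR, an inhibitor of death receptor signalling, was the 1 of 19 cell death genes that fell, with a log2 change of -1.15 ± 0.31 (SE), and its adjusted p was under 0.05 in 10 of 28 alternatives. ATP1B1, a subunit of the sodium pump, was the 1 of 16 ion and water transport genes that rose, by 1.32 on the log2 scale, and was past the threshold in 14 of 28 alternatives; without healthy region 2 its change was 0.34 (adjusted p = 0.919). P-values over regions are too small if regions share a person.

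Splicing and nuclear speckle genes were lower in IPF regions. The list of 48 genes was written after some of its members had been seen among the called genes. Of these, 46 had a log2 change below 0, 6 fell and 0 rose, with a median of -0.63. Without the genes that fell, the remaining 42 had a median of -0.57, below a level-matched range of -0.51 to -0.29. The median of the matched lists, -0.41, was also below 0, and the range is too narrow if the splicing genes move together. As a hypothesis, transcripts of splicing factors may be lower in these IPF regions beyond other genes of their level, which a difference in RNA quality between tissue blocks, not tested, could also give.

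PTBP1, a splicing regulator on the same list, was singled out after its values were seen. Its value was 193 ± 19.6 in healthy regions (SD, n = 3) and 607 ± 213 in IPF regions (SD, n = 8), and all 8 IPF regions lay above the healthy ones. The log2 change of 1.56 ± 0.68 (SE) was not called by limma (adjusted p = 0.418) or edgeR (adjusted p = 0.121). Relative to the median gene its reads were 2.99 times higher in IPF regions, which repeats the rise it was singled out for, so whether its probe follows the background of the region stays open.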
